A study of Escherichia coli K-12 with 15 samples.

How the data were processed

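RNA from 15 cultures of Escherichia coli K-12 was measured by strand-specific RNA sequencing after removal of ribosomal RNA, with 3 replicate cultures in each of 5 groups. The wild-type strain GJ13519 was grown in glucose minimal medium (WT_glucose) or in 0.2% glycerol minimal medium (WT_glycerol). The other groups were grown in glucose and express UvsW, a phage helicase that unwinds R-loops: the wild type GJ13533 (WT_UvsW), the deletion strain GJ13531 (drho_UvsW) and the nusG deletion GJ13507 (dnusG_UvsW). IPTG was at 200 µM except in dnusG_UvsW, where it was at 3 µM. Both deletion strains were inoculated at 1:50 and the other cultures at 1:100, into 20 ml, and were taken for RNA once the A600 lay between 0.4 and 0.45. The IPTG level and the inoculum are therefore not separable from the genotype in the comparisons they differ in.

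Per the submitters' processing notes, the authors used bcl2fastq 2.15.0, FastQC 0.11.5, cutadapt 1.9.1, Bowtie2 and SAMtools, the last pair without a stated version. The deposited values are signal, in the form of raw base read counts per open reading frame (ORF) on the sense and on the antisense strand: the read bases summed over the positions of the ORF. A read adds up to its length, so a value is not a number of reads, and no counting interval can be taken from it. Among the 2905 values above 0 and below 800, 18.2% were multiples of 75. No normalization was applied by the authors. The genome build is not given in the sources used here, and the coordinates printed are the deposited ones. How bases were assigned where ORFs overlap is not stated either.

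The key above the deposited table describes the block headed GJ13507 as replicates of GJ13533, the strain of another block. The heading over the columns and the sample labels both give GJ13507 and were followed. In those columns nusG, which that strain lacks, stood at 9.28 to 10.9 ppm, and in the other 12 libraries at 541 or above. The deposited table had 4091 lines. For 19 b numbers it held several lines with identical values, so 21 repeats were dropped and 4070 ORFs were kept. Of these, 4015 b numbers matched a RefSeq gene table of the K-12 strain, whose symbols helped to find list members. Printed gene names are the deposited ones. Neighbours were taken from the deposited coordinates and strands of the 4070 ORFs, so a gene absent from that table was never counted as a neighbour. All 30 value columns were used. Sense base counts summed to between 1.87 and 3.02 gigabases per library, and no library was left out.

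Size factors were medians of ratios over the sense values of the ORFs above 0 in every library. The same factors scaled both strands, so that a general rise of antisense RNA was kept. Scaled values are in ppm, parts per 1000000 of the scaled sense base counts. ORFs with at least 1 ppm in at least 3 libraries were tested, which kept 4066 ORFs for sense, 4053 for antisense and 4051 for the ratio of antisense to sense. Values were compared as log2 of the scaled value plus 0.5 with limma 3.58.1 (lmFit, then eBayes with trend and robust settings) and statmod 1.5.0 in R 4.3.3. All 15 libraries entered 1 fit with 5 group means and 10 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the ORFs of a strand in a comparison and a threshold of 0.05. An ORF is said to rise or fall only if it passed this test. The comparisons were drho_UvsW and dnusG_UvsW each against WT_UvsW, drho_UvsW against dnusG_UvsW, WT_UvsW against WT_glucose, and WT_glycerol against WT_glucose. Antisense shares and median ratios per library were compared by exact two-sided permutation tests of the means in scipy 1.17.1 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3), 3 libraries against 3, for which the smallest possible p is 0.1.

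The 23 gene lists included prophages (Rac, e14, Qin, DLP12, and CP4 with other cryptic elements), loci silenced by the nucleoid protein H-NS, the SOS response, sigma-32 heat shock, RpoS general stress, flagella and chemotaxis, ribosomal proteins, glycerol catabolism, catabolic genes activated by CRP-cAMP, the TCA cycle with the glyoxylate shunt, glycolysis with glucose uptake, amino acid biosynthesis, iron acquisition, R-loop and topology enzymes, transcription elongation and termination, type II toxin-antitoxin pairs, the colanic acid capsule and the lac operon. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists of a strand and comparison. A list is said to be called by the camera test at the preset correlation, and the fry results are not printed. The lac operon had 0 of its 4 members in the table and was not analysed. The Rac list had 5 of 31 members in the table. Named genes per comparison were the 8 largest rises and 8 largest falls on the sense strand (5 and 5 for drho_UvsW against dnusG_UvsW), among called ORFs whose 3 libraries of one group all lay above the other 3 and whose higher mean was at least 20 ppm. On the antisense strand they were the 6 largest rises and 3 largest falls (3 and 3 for drho_UvsW against dnusG_UvsW) at 5 ppm or more. Insertion sequence genes were left out because their copies share reads. Up to 4 members per list with the smallest adjusted p were added, and nusG, rnhA, topA and recG in every comparison. 1 gene and 1 list that were tested, with the adjustments made over them as well, are not reported here. At least the upper part of each ranking is printed. These rules, the lists, the comparisons, the tests and the alternatives were fixed before the data were examined, except where an alternative is said to have been added.

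Further measures were the correlation of the deletion effects across ORFs, with values simulated 100 times for unchanged groups against the same controls, since both deletions share WT_UvsW. The antisense change was compared between ORFs with a convergent and with a codirectional 3′ neighbour by 100000 permutations of the class labels. Since neighbouring ORFs are not independent and the permutations leave out the spread between libraries, circular shifts of the classes along the chromosome and a comparison of the difference per library were added after seeing the data. Alternatives were scaling by total sense values, by total sense plus antisense values, by the 500 ORFs of highest mean sense value, and by the antisense strand itself; pseudocounts of 0.1 and 2; no filter and a filter of 5 ppm; a fit of the 6 compared libraries alone; voom weights; the replicate number as a block; and each replicate left out in turn. Whether replicate numbers pair the cultures was checked from the correlation of residuals. The method was tested on simulated data with changes placed in 200 ORFs per strand, 50 at each of 4 sizes. These ORFs had a WT_UvsW mean of at least 20 ppm for sense or 5 ppm for antisense. All ORFs of a strand were given the same dispersion. At 3 libraries against 3 it recovered 66.0% of the 2-fold sense rises, 68.0% of the 2-fold falls and 100% of the 4-fold changes, and called 9 of 3729 unchanged ORFs. On the antisense strand it recovered 74.0% of 2-fold rises but 46.0% of 2-fold falls, and 100% of the 4-fold changes, and called 6 of 3433 unchanged ORFs. In the simulation, which was of drho_UvsW against WT_UvsW, antisense falls of that size were thus missed more often than rises. Recovery at ORFs of lower value, with unequal spread or with most ORFs changed was not tested.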

Results

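The data are strand-specific base counts for 4070 ORFs of Escherichia coli K-12 in 15 cultures, 3 per group. Sense base counts per library, in gigabases, were 2.88, 2.65 and 3.02 in WT_glucose, 2.52, 2.99 and 3.01 in WT_glycerol, and 1.87, 2.45 and 2.60 in WT_UvsW. They were 2.70, 2.28 and 2.45 in drho_UvsW, and 2.55, 2.98 and 2.52 in dnusG_UvsW. Replicates of a group correlated across ORFs with Pearson's r between 0.970 and 0.996 on log2 sense values. The first principal component held 62.4% of the sense variance and placed the 6 deletion libraries apart from the 9 wild-type ones.

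Antisense RNA took 21.9% ± 0.497 (SD, n = 3) of all ORF base counts in drho_UvsW and 11.4% ± 0.413 (SD, n = 3) in dnusG_UvsW, which lacks the transcription elongation factor NusG. In the wild type WT_UvsW the share was 5.02% ± 0.473 (SD, n = 3). It was 4.09% ± 0.321 (SD, n = 3) in WT_glucose and 3.71% ± 0.589 (SD, n = 3) in WT_glycerol. The ratio of means to WT_UvsW was 4.37 for drho_UvsW and 2.26 for dnusG_UvsW, and the difference between the deletions was 10.6 percentage points. WT_UvsW lay 0.930 percentage points above WT_glucose. In these 4 comparisons the 3 libraries of one group lay above the 3 of the other. The exact permutation p was 0.1 for each, the smallest that 3 against 3 can give (adjusted 0.125 over 5 comparisons). WT_glycerol differed from WT_glucose by -0.383 percentage points, which was within the spread of replicates (exact permutation p = 0.4). The median ORF ratio of antisense to sense, as log2, was -1.42 ± 0.037 (SD, n = 3) in drho_UvsW, -2.37 ± 0.058 in dnusG_UvsW and -3.36 ± 0.117 in WT_UvsW. It was -3.62 ± 0.123 in WT_glucose and -3.83 ± 0.101 in WT_glycerol. Antisense exceeded sense at 1151 ± 32.4 of 4051 ORFs in drho_UvsW, at 719 ± 30.2 in dnusG_UvsW and at 478 ± 22.8 in WT_UvsW (mean ± SD, n = 3).

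**Figure D1:**
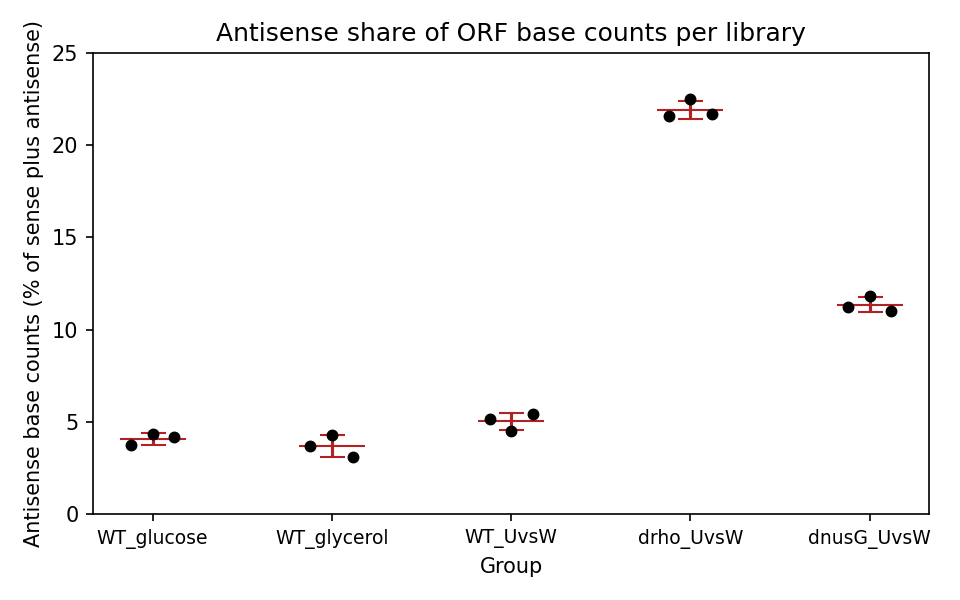
Antisense base counts in percent of sense plus antisense over all ORFs, by group; points are libraries, the red mark is the group mean and the bar is 1 SD (n = 3). The drho_UvsW libraries lie between 21.6% and 22.5%, the dnusG_UvsW libraries between 11.02% and 11.8%, and the WT_UvsW libraries between 4.49% and 5.40%.

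Sense values of nusG (b3982, positions 4175766 to 4176311) were 10.9, 10.01 and 9.28 ppm in dnusG_UvsW. They were 1033, 850.1 and 787 in WT_UvsW, 608, 541 and 661 in drho_UvsW, 673, 1037 and 750.0 in WT_glucose, and 744, 764 and 739.8 in WT_glycerol.

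The comparison of drho_UvsW with WT_UvsW asks how transcription on each strand differs between this deletion group and the wild type, both with UvsW. The lists of capsule genes, H-NS-silenced loci and the CP4 and DLP12 prophages gained sense RNA, while the TCA cycle with the glyoxylate shunt, the SOS response and RpoS-dependent stress genes lost it. Each of these 7 list calls was lost with an estimated correlation (adjusted p from 0.167 to 0.378 with an estimated correlation). The largest sense rises were in ygeK and ygeM, neighbouring ORFs, in yhcA and in ydeO, a regulator of acid resistance. Large falls were in aceB (malate synthase), rbsD (ribose uptake) and dps (DNA protection in starved cells). Antisense rises were largest at narJ, narI and narH of the nitrate reductase operon.

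In that comparison ygeK (b2855, positions 2992482 to 2992925) stood at 104 ± 17.7 ppm against 0.277 ± 0.0488 (mean ± SD, n = 3 each), a log2 fold change of 7.07 (SE 0.340, adjusted p = 1.41e-12). For ygeM (b2857, 2993336 to 2993767) the values were 159 ± 19.7 against 0.812 ± 0.481 and 6.98 (SE 0.576, adjusted p = 1.8e-07). For yhcA (b3215, 3360134 to 3360808) they were 622 ± 145 against 5.32 ± 1.76 and 6.77 (SE 0.430, adjusted p = 4.37e-09). For ydeO (b1499, 1580950 to 1581711) they were 263 ± 67.2 against 2.35 ± 0.301 and 6.50 (SE 0.267, adjusted p = 5.51e-14). Where a group mean lies near or under the pseudocount of 0.5, the fold change depends on that setting. Among the falls, the values were 61.4 ± 8.63 against 4078 ± 1060.0 for aceB (b4014, 4213501 to 4215102; -6.02, SE 0.187, adjusted p = 2.46e-15). They were 13.5 ± 6.66 against 883 ± 375 for rbsD (b3748, 3931374 to 3931793; -6.02, SE 0.349, adjusted p = 2.86e-10), and 20.7 ± 2.80 against 745 ± 206 for dps (b0812, 847631 to 848134; -5.11, SE 0.211, adjusted p = 3.8e-14).

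On the sense strand, 3166 of 4066 ORFs were called in drho_UvsW, 1555 up and 1611 down, of which 1238 rose and 859 fell at least 2-fold. This split depends on the scaling. The median log2 change of all ORFs moved from -0.10 to 0.53 with total sense values (2085 up, 736 down). It moved to 0.25 with sense plus antisense totals (1823 up, 1142 down) and to 0.83 with the 500 highest ORFs (2436 up, 426 down). Of the capsule genes for colanic acid, 21 of 22 rose and 0 fell (median log2 3.19), among them wza (4.57) and wzc (4.36), which export the polymer (adjusted p = 0.17 with an estimated correlation). Of the H-NS-silenced loci, 34 of 39 rose and 1 fell (2.53), with hlyE, a haemolysin, at 4.87 and gspF, of a secretion system, at 3.47 (adjusted p = 0.167 with an estimated correlation). Of CP4 and other cryptic prophages, 44 of 55 rose and 4 fell (2.07), with yfjI at 5.55 (adjusted p = 0.167 with an estimated correlation). Of DLP12 prophage genes, 21 of 27 rose and 3 fell (1.92), with ybcD at 6.27 (adjusted p = 0.17 with an estimated correlation). These 4 calls were thus lost with that setting.

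Among lists that fell in drho_UvsW, the SOS response had 21 of 26 members down and 1 up (median log2 -1.49), with recA at -3.35 and sulA, a division inhibitor, at -3.49 (adjusted p = 0.17 with an estimated correlation). These genes stood higher in the reference WT_UvsW than in WT_glucose (median log2 1.39), so they fell from a raised level. The deletions were not compared with WT_glucose. In WT_UvsW the medians against WT_glucose were also 0.541 for RpoS genes, 0.463 for heat shock, -0.865 for the TCA cycle and -0.477 for ribosomal proteins. The calls for these lists in that comparison were lost with an estimated correlation. The TCA cycle and glyoxylate shunt had 20 of 22 down and 0 up (-1.43), with aceA, isocitrate lyase, at -4.83 and icd at -2.59 (adjusted p = 0.17 with an estimated correlation). Glycolysis had 16 of 18 down and 1 up (-1.50), with fbaB at -3.52 and pgi at -2.61 (adjusted p = 0.189 with an estimated correlation). Amino acid biosynthesis had 48 of 69 down and 2 up (-1.08; thrB -2.91, thrC -2.73; adjusted p = 0.243 with an estimated correlation). RpoS general stress had 24 of 36 down and 6 up (-1.40; elaB -4.31, otsB -3.71) and heat shock 14 of 21 down and 1 up (-0.99; clpX -1.95). For the last 2, adjusted p = 0.378 and 0.457 with an estimated correlation. Ribosomal protein genes had 47 of 54 down and 0 up (-0.89; rpsL -1.20, rplX -1.03), but the median turned to 0.04 with the 500 highest ORFs, and adjusted p = 0.497 with an estimated correlation. With the 500 highest ORFs neither named gene passed the test (rpsL -0.26, rplX -0.09), and of the list 1 fell and 1 rose. The other falls shrank with that scaling as well. The median was -0.14 for amino acid biosynthesis (20 down, 20 up) and -0.05 for heat shock (5 down, 5 up). It was -0.55 for SOS genes (14 down, 5 up), -0.50 for the TCA cycle (11 down, 3 up), -0.56 for glycolysis (10 down, 3 up) and -0.46 for RpoS genes (18 down, 12 up).

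The other lists had no camera call on the sense strand in drho_UvsW. For flagella, e14 and CRP-cAMP genes the reference WT_UvsW itself differed from WT_glucose (median log2 -2.79, 0.705 and -0.364). Members moved both ways among flagella and chemotaxis (22 of 52 rose, 8 fell; fliT 2.37, fliC, the filament, -1.55) and catabolic genes activated by CRP-cAMP (33 of 64 rose, 23 fell; rbsA -4.75). They also did so in glycerol catabolism (5 of 9 rose, 2 fell; glpA 5.05), e14 (14 of 27 rose, 9 fell; pin 3.40, ymfJ -4.79) and Qin (19 of 36 rose, 5 fell; ynfO 5.52). For iron acquisition (3 of 38 rose, 15 fell; fepE 1.85), R-loop and topology enzymes (2 of 17 rose, 9 fell; gyrA -1.54), Rac (0 of 5 rose, 2 fell; stfR -5.03), transcription elongation and termination (2 of 20 rose, 12 fell; ydgT 2.02) and toxin-antitoxin pairs (4 of 22 rose, 13 fell; yafN -2.02), the median was negative but turned positive with at least 1 other scaling. The transcription list as fixed held ydgT, which encodes an H-NS partner. With the 500 highest ORFs 45 flagellar genes rose and 1 fell. With that scaling 42 CRP-cAMP genes rose and 10 fell, and 17 e14 genes rose and 4 fell. Glycerol genes then had 8 up and 0 down and Qin 28 up and 0 down, so these lists no longer moved both ways. The helicase gene recG rose by 1.25 (SE 0.171, adjusted p = 1.56e-06). Topoisomerase I (topA) fell by 1.01 (adjusted p = 1.25e-05) and ribonuclease HI (rnhA) fell by 0.951 (adjusted p = 0.000762), though neither passed with the 500 highest ORFs (topA -0.07, rnhA -0.02). The nusG gene fell by 0.555 (adjusted p = 0.00653), with the direction turned to 0.08 with total sense values and to 0.38 with the 500 highest ORFs. Adjusted over the list alone, the counts were the same except in 6 lists. Amino acid biosynthesis had 47 down, CP4 5 down, CRP-cAMP 34 up, flagella 21 up and 7 down, iron 11 down and RpoS 7 up.

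On the antisense strand, 3437 of 4053 ORFs were called in drho_UvsW, 3089 up and 348 down, with a median log2 change of 1.85 that ranged up to 2.72 with the other scalings from sense or total values. The falls were fewer with these, 145 with total sense values (3472 up), 217 with sense plus antisense totals (3324 up) and 91 with the 500 highest ORFs (3609 up). Scaled by the antisense values themselves, which removes a general rise, 1639 went up and 1516 down (median 0.06). The largest rises were in narJ (b1226, positions 1284362 to 1285072), at 494.5 ± 2.80 against 0.511 ± 0.163 ppm (log2 8.95, SE 0.461, adjusted p = 6.32e-12). Next were narI (b1227, 1285072 to 1285749), at 978 ± 106 against 2.04 ± 0.766 (8.63, SE 0.612, adjusted p = 6.56e-09), and narH (b1225, 1282827 to 1284365), at 974 ± 64.8 against 2.07 ± 0.352 (8.57, SE 0.559, adjusted p = 1.24e-09). Antisense fell at the e14 gene ymfI (b1143, 1200720 to 1201061), at 2.47 ± 0.238 against 63.2 ± 33.3 (-4.24, SE 0.321, adjusted p = 4.82e-11). Antisense rose at 53 of 56 CP4 and other cryptic prophage genes (yfdO 4.98), 26 of 27 DLP12 genes (ybcQ 6.22, with 1 down) and 38 of 39 H-NS-silenced loci (ygcL 5.55), with adjusted p = 0.287, 0.304 and 0.34 with an estimated correlation. It rose also at 22 of 22 capsule genes (wcaE 4.59) and 51 of 52 flagellar genes (tsr 6.02). For this pair, adjusted p = 0.34 and 0.616 with an estimated correlation. It fell at 47 of 54 ribosomal protein genes and rose at 0 (median -1.96; rpsH -2.24, rplB -2.16), with adjusted p = 0.287 with an estimated correlation. Of these genes 35 fell and 3 rose with the 500 highest ORFs (-1.06). Medians also lay below that of all ORFs for glycolysis (9 of 18 down, 4 up; pfkB 2.89), Rac (1 of 5 down, 1 up), and transcription elongation and termination (6 of 20 down, 7 up), each with adjusted p = 0.287 with an estimated correlation. The same held for amino acid biosynthesis (17 of 69 down, 30 up; metH 3.97), the TCA cycle (5 of 22 down, 6 up; icd -3.13) and heat shock (6 of 21 down, 11 up). For the last 3, adjusted p = 0.304, 0.34 and 0.34 with an estimated correlation. The sign of the median of the TCA, glycolysis, transcription and Rac lists changed with the scaling. Scaled by the 500 highest ORFs, the counts were 4 down and 48 up for amino acid genes, 1 down and 12 up for the TCA cycle, and 1 down and 15 up for heat shock. They were 1 down and 6 up for glycolysis, 1 down and 4 up for Rac, and 2 down and 11 up for transcription elongation. Adjusted over the list alone the counts for these lists were the same, except 16 down for amino acid biosynthesis.

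The ratio of antisense to sense was called for 3140 of 4051 ORFs in drho_UvsW, 2698 up and 442 down, with a median log2 change of 1.48. Across ORFs, which are not independent replicates, the antisense change was larger where the WT_UvsW sense level was lower (Pearson's r -0.638, Spearman's -0.641). It was also larger where the WT_UvsW antisense level, which enters the fold change itself, was lower (Pearson's r -0.605, Spearman's -0.599). The median antisense log2 change was 3.39 in the lowest quintile by sense level, 2.65, 1.93 and 1.28 in the next ones and -0.08 in the highest, where 34.4% of the ORFs rose. Quintiles were computed with the size factors alone. Over all ORFs the median went from 1.85 up to 2.72 with other scalings, so the sign in the highest quintile is not settled. ORFs whose 3′ neighbour is convergent had a smaller median antisense change than those with a codirectional neighbour, 1.59 over 1198 ORFs against 1.995 over 2855. The share of ORFs that rose did not follow the median, at 77.4% for convergent and 75.7% for codirectional neighbours, and 77.2% for each within 200 bases. The difference was -0.41, with permutation p = 1e-05, the smallest that 100000 permutations can give (adjusted 1.7e-05 over 5 comparisons). That test takes ORFs as independent, which neighbours are not. Circular shifts of the classes along the chromosome gave a permutation p = 0.00025, the smallest that 4053 shifts can give. Without any 1 of the 6 libraries the difference lay between -0.465 and -0.344, and compared per library it had an exact permutation p of 0.1. The neighbour classes were not matched for starting level, here or in the other comparisons. An effect of orientation therefore cannot be told apart from a difference in level.

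**Figure D2:**
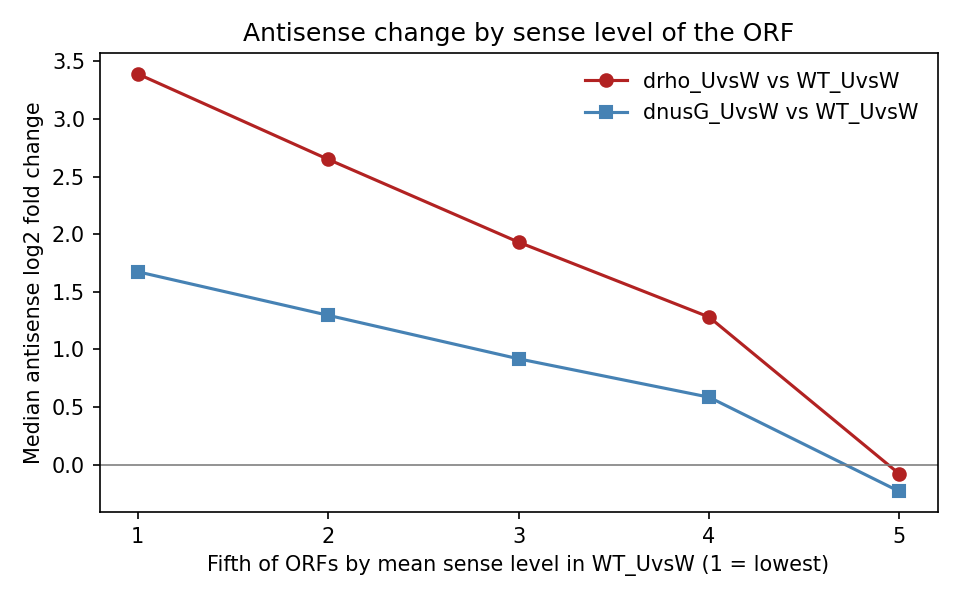
Median antisense log2 fold change against WT_UvsW of ORFs grouped in quintiles by their mean sense level in WT_UvsW, from lowest to highest, for both deletions. The medians run from 3.39 to -0.08 in drho_UvsW and from 1.67 to -0.23 in dnusG_UvsW. They were computed with the size factors alone, and other scalings from sense or total values raise the median of all ORFs.

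The comparison of dnusG_UvsW with WT_UvsW asks the same of the loss of NusG; the IPTG level differs as well and cannot be separated from it. Genes of the Qin prophage, among them dicB, an inhibitor of cell division, and the capsule genes gained sense RNA, while flagellar genes, amino acid biosynthesis and RpoS-dependent genes lost it. Each of these 5 list calls was lost with an estimated correlation (adjusted p from 0.222 to 0.388 with an estimated correlation). The largest fall was in flu, which encodes the surface adhesin antigen 43. Antisense RNA rose most at yqiH, yafU and yhiF.

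In that comparison ydfD (b1576, positions 1647818 to 1648009) stood at 120.0 ± 18.9 ppm against 0.313 ± 0.228 (mean ± SD, n = 3 each), a log2 fold change of 7.24 (SE 0.319, adjusted p = 9.56e-13). For ydfE (b1577, 1648102 to 1649022) the values were 1149 ± 109 against 8.18 ± 3.90 and 7.14 (SE 0.361, adjusted p = 1.01e-10). For dicB (b1575, 1647633 to 1647821) they were 80.2 ± 9.97 against 0.266 ± 0.224 and 6.75 (SE 0.308, adjusted p = 9.56e-13). For ydfA (b1571, 1646532 to 1646687) they were 342 ± 15.5 against 3.48 ± 0.923 and 6.45 (SE 0.349, adjusted p = 8.1e-11). The largest falls were flu (b2000, 2069563 to 2072682), at 20.5 ± 2.31 against 3182 ± 836 (-7.22, SE 0.177, adjusted p = 5.93e-17), and nusG itself, at 10.1 ± 0.810 against 890.0 ± 128 (-6.39, SE 0.173, adjusted p = 2.02e-16). They were followed by ycaC (b0897, 944154 to 944780), at 7.15 ± 0.872 against 548 ± 116 (-6.15, SE 0.225, adjusted p = 2.87e-14), and the Rac gene stfR (b1372, 1427073 to 1430435), at 0.216 ± 0.0967 against 26.02 ± 9.32 (-5.17, SE 0.263, adjusted p = 2.35e-12). The gene stfR also fell in drho_UvsW, and the Rac list had 5 of its 31 members in the table. RNA values alone cannot tell a lowered expression of stfR from its absence in the deletion strains.

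On the sense strand, 2819 of 4066 ORFs were called in dnusG_UvsW, 1407 up and 1412 down, of which 951 rose and 704 fell at least 2-fold. The median log2 change of all ORFs moved from -0.03 to 0.45 with total sense values (1974 up, 755 down). It moved to 0.35 with sense plus antisense totals (1841 up, 865 down) and to 0.60 with the 500 highest ORFs (2190 up, 598 down). The capsule genes all rose, 22 of 22 (median log2 2.54; wcaE 3.63, gmd 3.51), as did 32 of 39 H-NS-silenced loci with 3 down (1.49; bglH 3.75, gspA 3.11), each with adjusted p = 0.222 with an estimated correlation. So did 21 of 27 DLP12 genes with 2 down (1.37; ybcK 4.49; adjusted p = 0.222 with an estimated correlation). Of Qin genes, 23 of 36 rose and 1 fell (2.29; dicC 5.18), with adjusted p = 0.232 with an estimated correlation. Of flagella and chemotaxis genes 34 of 52 fell and 5 rose (-1.02; flgD -3.08, flgE -2.79; adjusted p = 0.232 with an estimated correlation). Of SOS genes 17 of 26 fell and 3 rose (-0.74; sulA -3.12, recA -2.29), and of glycolysis genes 14 of 18 fell and 0 rose (-1.39; fbaB -3.74, and the glucose transporter ptsG -2.54), each with adjusted p = 0.232 with an estimated correlation. Amino acid biosynthesis had 55 of 69 down and 2 up (-1.22; thrB -3.19) and the TCA cycle 15 of 22 down and 3 up (-0.94; icd -2.33), with adjusted p = 0.222 and 0.278 with an estimated correlation. RpoS general stress had 25 of 36 down and 8 up (-1.65; elaB -3.86, talA -4.36) and heat shock 13 of 21 down and 1 up (-1.45; clpX -1.45). Here adjusted p = 0.388 and 0.415 with an estimated correlation. Ribosomal protein genes had 29 of 54 down and 0 up (-0.55; rplY -1.44), turning to 0.10 with the 500 highest ORFs (5 down, 4 up), and adjusted p = 0.609 with an estimated correlation. That scaling moved the other falls too. The median was -0.09 for SOS genes (12 down, 8 up), -0.30 for the TCA cycle (7 down, 4 up), -0.40 for flagella (23 down, 14 up) and -0.57 for amino acid biosynthesis (34 down, 5 up). It was -0.74 for glycolysis (12 down, 4 up), -0.80 for heat shock (12 down, 5 up) and -1.01 for RpoS genes (20 down, 9 up). Adjusted over the list alone these counts were the same, except 35 down for flagella, 16 down for the TCA cycle and 28 down for ribosomal proteins. The reference WT_UvsW itself differed from WT_glucose in SOS genes (median log2 1.39) and flagella (-2.79). Its medians against WT_glucose were 0.541 for RpoS genes, 0.463 for heat shock, -0.865 for the TCA cycle and -0.477 for ribosomal proteins. The calls for these lists in that comparison were lost with an estimated correlation. The H-NS partners ydgT and hha rose by 3.63 and 2.64. Of the R-loop enzymes, topA fell by 0.773 (adjusted p = 0.000297), but did not pass with total sense values (-0.28) or with the 500 highest ORFs (-0.13). The values of recG (-0.14, adjusted p = 0.472) and rnhA (-0.003, adjusted p = 0.992) did not pass, and both were positive under 3 other scalings.

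On the antisense strand, 2864 of 4053 ORFs were called in dnusG_UvsW, 2492 up and 372 down, with a median log2 change of 0.87 that ranged up to 1.44 with the other scalings from sense or total values. There were 177 falls with total sense values (3093 up), 211 with sense plus antisense totals (2987 up) and 120 with the 500 highest ORFs (3214 up). Scaled by the antisense values, 1319 went up and 1184 down (median 0.07). The largest rises were in yqiH (b3047, positions 3187903 to 3188652), at 226.5 ± 15.9 against 2.91 ± 1.02 ppm (6.10, SE 0.412, adjusted p = 6.51e-10). They were followed by yafU (b0218, 238746 to 239084), at 36.5 ± 5.74 against 0.306 ± 0.225 (5.54, SE 0.356, adjusted p = 5.31e-11), and yhiF (b3507, 3652706 to 3653236), at 134 ± 24.6 against 2.41 ± 0.541 (5.53, SE 0.259, adjusted p = 1.86e-13). The largest falls were in ymfI, at 1.904 ± 0.521 against 63.2 ± 33.3 (-4.56, SE 0.321, adjusted p = 1.03e-10), and nusG (-4.28). Antisense rose at 39 of 39 H-NS-silenced loci (appY 4.51, hchA 3.38) and 47 of 56 CP4 and other cryptic prophage genes (ykfH 4.41, with 1 down), each with adjusted p = 0.351 with an estimated correlation. It rose at 22 of 27 DLP12 genes with 2 down, 21 of 22 capsule genes and 28 of 36 Qin genes (ydfE 4.08), with adjusted p = 0.497, 0.558 and 0.637 with an estimated correlation. Antisense at malG, a maltose transporter gene, rose by 5.26. It fell at 35 of 54 ribosomal protein genes and rose at 1 (-1.21; rpsC -1.68, rplP -1.53; adjusted p = 0.351 with an estimated correlation), though at 8 and 2 with the 500 highest ORFs (-0.57). Amino acid biosynthesis (28 of 69 down, 14 up; thrA -2.67), heat shock (8 of 21 down, 7 up; groS -3.32), glycolysis (8 of 18 down, 4 up), the TCA cycle (8 of 22 down, 4 up) and Rac (2 of 5 down, 2 up) also lay below all ORFs. For these 5 lists, too, adjusted p = 0.351 with an estimated correlation, and the sign of the median of amino acid, heat shock and TCA genes changed with the scaling. Scaled by the 500 highest ORFs, the counts were 12 down and 30 up for amino acid genes, 4 down and 8 up for heat shock, 2 down and 8 up for glycolysis, 4 down and 7 up for the TCA cycle, and 2 down and 3 up for Rac. Adjusted over the list alone the counts differed for CP4 (50 up), amino acid (26 down) and TCA genes (7 down). The ratio was called for 2300 ORFs, 1926 up and 374 down (median 0.70). The antisense change was again larger at lower sense levels (across ORFs, Pearson's r -0.555, Spearman's -0.556) and at lower WT_UvsW antisense levels (-0.412 and -0.388). By sense level it had a median of 1.67 in the lowest quintile and -0.23 in the highest. These, too, were computed with the size factors alone, so the sign in the highest is not settled. Between ORFs with a convergent neighbour (0.93) and a codirectional one (0.85) the difference did not pass the permutation test (p = 0.12, and 0.16 by circular shifts). There 63.4% and 60.7% rose.

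Effects of both deletions were compared across ORFs. Sense fold changes correlated with r = 0.740 (Spearman's 0.751) against 0.502 in simulations where the comparisons are linked by their shared controls alone. The covariance was 1.97 against 0.029 simulated. Of the called ORFs, 1109 rose in both (538 expected from the totals) and 1057 fell in both (559 expected). With sense plus antisense totals 1397 rose in both (825 expected) and 576 fell in both (243 expected). On the antisense strand r was 0.657 (Spearman's 0.649; 0.5 simulated) with a covariance of 1.47 against 0.037. There 2325 ORFs rose in both (1899 expected) and 201 fell in both (32 expected). With sense plus antisense totals 2807 rose in both (2448 expected) and 94 fell in both (11 expected). All expected counts take the comparisons as independent. The shared controls link them, so these are not the counts for unchanged groups, and the size of the excess is not measured.

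The direct comparison of drho_UvsW with dnusG_UvsW asks where the deletions differ. The glyoxylate shunt genes aceB and aceA, the SOS genes lexA and recA, and Qin genes such as ydfA and dicC were lower in drho_UvsW. Flagellar genes, e14 and CP4 prophage genes, the glycerol phosphate dehydrogenase gene glpA and hlyE were higher. The list calls for SOS, Qin, flagellar, e14 and CP4 genes were lost with an estimated correlation (adjusted p from 0.244 to 0.26 with an estimated correlation). Apart from nusG (5.84) the largest sense rises were atoD (b2221, positions 2321469 to 2322131), of acetoacetate degradation, at 48.3 ± 3.07 against 0.594 ± 0.271 ppm (mean ± SD, n = 3 each; log2 5.51, SE 0.251, adjusted p = 6.97e-13), and ybcD (b4508, 565674 to 565910), at 226.5 ± 23.2 against 4.57 ± 0.212 (5.48, SE 0.242, adjusted p = 5e-13). Among the falls were aceB, at 61.4 ± 8.63 against 4366 ± 178 (-6.15, SE 0.187, adjusted p = 1.47e-15), and ydfA, at 4.96 ± 0.814 against 342 ± 15.5 (-5.98, SE 0.349, adjusted p = 2.74e-10).

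In that comparison 2419 sense ORFs were called, 1344 up and 1075 down (876 and 398 at least 2-fold). With the 500 highest ORFs 1718 went up and 656 down, as the median of all ORFs moved from 0.03 to 0.31. It was 0.17 with total sense values. CP4 and other cryptic prophage genes were higher at 38 of 55 and lower at 1 (adjusted p = 0.244 with an estimated correlation). Higher also were 35 of 52 flagellar genes with 2 lower (flgD 3.47, flgE 3.34), 17 of 27 e14 genes with 2 lower and 6 of 9 glycerol genes with 0 lower (glpA 4.44; 8 up adjusted over the list alone), each with adjusted p = 0.259 with an estimated correlation. Lower were 17 of 26 SOS genes with 2 higher (lexA -1.88, recA -1.07; 19 down adjusted over the list alone) and 11 of 20 transcription elongation genes with 2 higher (12 down adjusted over the list alone). For this pair, too, adjusted p = 0.259 with an estimated correlation. Qin had 19 of 36 lower and 4 higher (dicC -4.14; adjusted p = 0.26 with an estimated correlation). The TCA cycle had 9 of 22 lower and 4 higher (aceA -5.52; adjusted p = 0.475 with an estimated correlation), and iron acquisition 15 of 38 lower and 2 higher (14 lower adjusted over the list alone; adjusted p = 0.635 with an estimated correlation). H-NS-silenced loci had 20 of 39 higher and 8 lower (hlyE 3.38) and R-loop enzymes 9 of 17 lower and 2 higher, each with adjusted p = 0.484 with an estimated correlation. Ribosomal proteins had 9 of 54 lower and 0 higher (1 lower adjusted over the list alone; adjusted p = 0.755 with an estimated correlation). With the 500 highest ORFs the TCA cycle had 5 lower and 6 higher (median -0.08 against -0.37), ribosomal proteins 3 lower and 3 higher (-0.03 against -0.33), R-loop enzymes 6 lower and 2 higher (-0.23 against -0.52) and SOS genes 12 lower and 3 higher (-0.32 against -0.605). H-NS-silenced loci had 23 higher and 2 lower with that scaling, and 21 higher and 2 lower with total sense values. The value of recG was 1.39 (adjusted p = 7.66e-07) and that of rnhA -0.95 (adjusted p = 0.00122), while topA at -0.23 did not pass (adjusted p = 0.226; 0.06 with the 500 highest ORFs).

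Antisense was called at 2710 ORFs between the deletions, 2316 higher and 394 lower in drho_UvsW, with a median log2 difference of 0.79 (1.08 with the 500 highest ORFs, where 2702 were higher and 238 lower). Scaled by the antisense values, 1279 were higher and 1464 lower (median -0.15). It was highest by difference at narI (8.53, SE 0.612, adjusted p = 1.88e-08) and narJ (8.21, SE 0.461, adjusted p = 7.73e-11). Antisense of recB (5.52), ybcC (6.13) and fhuD (5.12) was higher as well, while that of ynfP (b4534, positions 1650752 to 1650862; -3.18, SE 0.222, adjusted p = 2.1e-11) was lower. Capsule (20 of 22 higher), CP4 (39 of 56; 40 adjusted over the list alone), DLP12 (21 of 27) and flagellar genes (38 of 52, 1 lower) stood above the other ORFs, with adjusted p = 0.733 for the first 3 and 0.906 for the last with an estimated correlation. Ribosomal protein (12 of 54 lower, 0 higher; 2 lower adjusted over the list alone), transcription elongation (10 of 20 lower, 4 higher) and glycolysis genes (4 of 18 lower, 5 higher; 4 higher adjusted over the list alone) stood below, the last with a median whose sign changed with the scaling. Lower ribosomal protein genes numbered 20 with sense plus antisense totals and 2 with the 500 highest ORFs, and lower glycolysis genes 2 with the latter. For these 3 lists, adjusted p = 0.733 with an estimated correlation. The ratio was called for 2531 ORFs, 1900 up and 631 down (median 0.64). ORFs with a convergent neighbour differed less between the deletions (0.56) than those with a codirectional one (0.93; 50.1% against 60.1% higher; permutation p = 1e-05, and 0.00025 by circular shifts), by between -0.389 and -0.335 without any 1 library, and the values per library had an exact permutation p of 0.1.

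**Figure D3:**
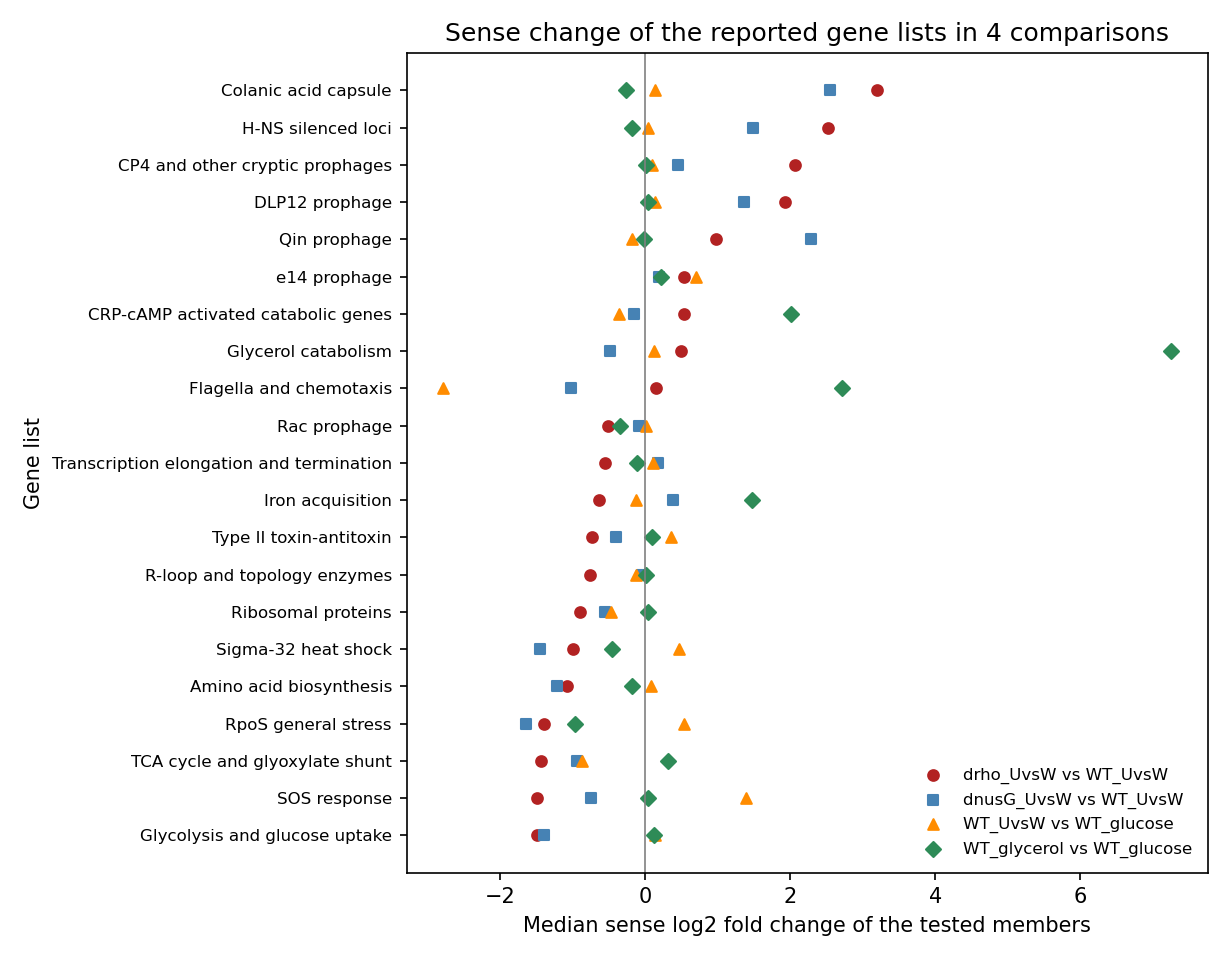
Median sense log2 fold change of the tested members of each reported gene list in 4 comparisons, 1 symbol per comparison, with lists ordered by the drho_UvsW value. Capsule genes lie at 3.19 and 2.54 in the deletions and glycerol genes at 7.25 in WT_glycerol. The medians of ribosomal proteins and of several other lists change sign with the scaling, among them R-loop enzymes at -0.758 in drho_UvsW.

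The comparison of WT_UvsW with WT_glucose asks what UvsW expression does in cells without either deletion. These groups are different strains, so UvsW expression cannot be separated from any other difference between the strains. SOS genes rose and flagellar genes fell. The largest rises were in prophage genes, ybcC of DLP12 and ymfT, ymfJ and ymfM of e14, followed by the SOS genes recN and umuD. The largest falls were in ybhC, in glnK and amtB of ammonium uptake and in gatD of galactitol use. For ybcC (b0539, positions 565321 to 565584) the values were 103 ± 33.1 against 2.93 ± 0.534 ppm (mean ± SD, n = 3 each; log2 4.87, SE 0.233, adjusted p = 3.82e-12). The values were, for ymfT (b1146, 1202247 to 1202447) 26.5 ± 9.01 against 0.632 ± 0.249 (4.55, SE 0.260, adjusted p = 4.25e-11) and, for ymfJ (b1144, 1200999 to 1201307) 160.5 ± 32.1 against 6.64 ± 0.804 (4.48, SE 0.182, adjusted p = 5.44e-13). For ymfM (b1148, 1203045 to 1203383) they were 59.6 ± 18.8 against 2.35 ± 0.908 (4.40, SE 0.237, adjusted p = 1.85e-11). For ybhC (b0772, 805221 to 806504) they were 4.79 ± 1.23 against 234.5 ± 33.8 (-5.49, SE 0.176, adjusted p = 1.12e-14) and for glnK (b0450, 471822 to 472160) 10.6 ± 5.27 against 297 ± 213 (-4.53, SE 0.700, adjusted p = 0.000694). For gatD (b2091, 2169857 to 2170897) they were 98.2 ± 16.3 against 1381 ± 280.0 (-3.80, SE 0.174, adjusted p = 2.69e-12) and for amtB (b0451, 472190 to 473476) 46.1 ± 9.16 against 766 ± 525 (-3.74, SE 0.626, adjusted p = 0.00126).

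Of flagella and chemotaxis genes, 51 of 52 fell and 0 rose in WT_UvsW (median log2 -2.79; fliC -3.69, cheA -3.50), a call that held with an estimated correlation (adjusted p = 0.000397). Of SOS genes 21 of 26 rose and 0 fell (1.39; 22 up adjusted over the list alone), with recN at 3.97, umuD at 3.68 and sulA at 2.88, and this call held as well (adjusted p = 0.00684 with an estimated correlation). Of catabolic genes activated by CRP-cAMP, 24 of 64 fell and 6 rose (-0.36; 25 down and 10 up adjusted over the list alone), with gatC at -2.70 and malE at -2.44, which also held (adjusted p = 0.029 with an estimated correlation). The TCA cycle had 11 of 22 down and 0 up (14 down and 1 up adjusted over the list alone; sucC -1.89, sucD -1.90) and e14 15 of 27 up and 4 down (5 down adjusted over the list alone), each with adjusted p = 0.0983 with an estimated correlation. RpoS genes had 17 of 36 up and 7 down (20 up adjusted over the list alone; osmB 1.55, gadC -2.21), heat shock had 3 of 21 up and 0 down, and ribosomal proteins 3 of 54 down and 0 up (0 adjusted over the list alone), each with adjusted p = 0.911 with an estimated correlation. The toxin-antitoxin gene yafN rose by 1.91. In all, 872 sense ORFs were called, 461 up and 411 down (151 and 207 at least 2-fold). The median of all ORFs moved from 0.07 to 0.16 with total sense values (606 up, 345 down) and to 0.21 with the 500 highest ORFs (757 up, 327 down). The balance turned with the 6 compared libraries alone (226 up, 309 down, 535 in all, median 0.02) and without WT_UvsW replicate 1 (315 up, 359 down, median 0.03). None of nusG (0.13, adjusted p = 0.62), topA (0.01, 0.978), recG (0.24, 0.346) and rnhA (-0.29, 0.379) passed the test.

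In WT_UvsW, 489 antisense ORFs were called, 391 up and 98 down (median 0.22; 104 up and 178 down when scaled by the antisense values). With the 6 compared libraries alone 105 went up and 77 down, and with the 500 highest ORFs 790 up and 90 down. There were 331 for the ratio, 255 up and 76 down (median 0.17), but 94 up and 33 down with the 6 libraries alone and 147 up and 38 down with voom weights. The largest rises lay side by side at the galactose transport genes: mglB (b2150, positions 2237372 to 2238370), at 96.1 ± 36.1 against 0.718 ± 0.0662 ppm (6.23, SE 0.247, adjusted p = 2.56e-14). Beside it were mglA (b2149, 2235791 to 2237311), at 130.2 ± 36.8 against 2.97 ± 1.19 (5.25, SE 0.271, adjusted p = 3.79e-12), and the repressor gene galS (b2151, 2238650 to 2239690), at 80.1 ± 27.5 against 2.51 ± 0.498 (4.69, SE 0.253, adjusted p = 6.19e-12). Antisense fell most at gatD (-2.59, SE 0.272, adjusted p = 1.24e-06) and intG (b1936, 2010526 to 2010804; -2.44, SE 0.293, adjusted p = 7.39e-06). Antisense fell at 28 of 52 flagellar genes (29 adjusted over the list alone; flgI -1.99, flgK -2.25; adjusted p = 0.152 with an estimated correlation) and at 9 of 22 TCA genes with 1 up (11 down and 4 up adjusted over the list alone; sucC -1.84; adjusted p = 0.607 with an estimated correlation). It rose at 13 of 26 SOS genes (17 up and 1 down adjusted over the list alone; recA 2.55, sulA 2.16), with adjusted p = 0.607 with an estimated correlation. Camera also called heat shock (8 of 21 up, 11 adjusted over the list alone), capsule (2 of 22 up, 4 adjusted over the list alone) and ribosomal protein genes (0 of 54 up or down), each with adjusted p = 0.853 with an estimated correlation. Single libraries moved these counts: without WT_UvsW replicate 1, 182 antisense ORFs went up and 72 down, without WT_glucose replicate 1, 178 up and 90 down (median 0.14), and without WT_UvsW replicate 3 the ratio was called for 533, 354 up and 179 down (median 0.105). The ratio had 394 up without WT_UvsW replicate 2 and 46 down without WT_glucose replicate 2. Antisense rose at 7 capsule genes and 4 TCA genes with the 500 highest ORFs. ORFs with a convergent neighbour had a median of 0.24 against 0.20 for codirectional ones, a difference of 0.04 (permutation p = 0.0061, adjusted 0.0076; 0.012 by circular shifts). This difference was within the spread of libraries. Compared per library it had an exact permutation p of 0.7, and it turned to -0.029 without WT_glucose replicate 2 and was 0.095 without WT_UvsW replicate 1.

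The comparison of WT_glycerol with WT_glucose gives the effect of the carbon source in a single strain. All 9 listed genes of glycerol uptake and breakdown rose, together with flagellar genes and genes activated by CRP-cAMP, while hdeD, gadA and gadB, known from acid resistance, and the glucose transporter gene ptsG fell. The glycerol-3-phosphate transporter gene glpT (b2240, positions 2349038 to 2350396) stood at 7476 ± 291 against 18.9 ± 3.25 ppm (mean ± SD, n = 3 each; log2 8.61, SE 0.189, adjusted p = 3.46e-18). Then came glpA (b2241, 2350669 to 2352297) at 789 ± 50.7 against 2.02 ± 1.11 (8.38, SE 0.261, adjusted p = 1.77e-15) and the kinase gene glpK (b3926, 4113737 to 4115245) at 11200 ± 416 against 48.0 ± 3.36 (7.85, SE 0.148, adjusted p = 3.28e-19). The gene glpB (b2242, 2352287 to 2353546) stood at 787 ± 76.3 against 4.48 ± 1.85 (7.38, SE 0.222, adjusted p = 6.09e-16). The largest falls were hdeD (b3511, 3655018 to 3655590), at 9.15 ± 0.429 against 128 ± 34.9 (-3.70, SE 0.211, adjusted p = 3.09e-11), and glnK, at 18.7 ± 1.46 against 297 ± 213 (-3.62, SE 0.700, adjusted p = 0.00184). They were followed by the glutamate decarboxylase genes gadA (b3517, 3664203 to 3665603), at 15.5 ± 0.891 against 190.4 ± 88.4 (-3.49, SE 0.239, adjusted p = 4.57e-10), and gadB (b1493, 1568669 to 1570069), at 23.4 ± 0.990 against 276 ± 101 (-3.48, SE 0.201, adjusted p = 3.45e-11).

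Of glycerol catabolism genes 9 of 9 rose in WT_glycerol (median log2 7.25), of flagellar genes 52 of 52 (median log2 2.72; cheY 3.20, tap 3.09) and of CRP-cAMP genes 52 of 64 with 2 down (2.01; cstA 3.92, acs 3.13; 54 up and 3 down adjusted over the list alone). Each of these calls held, with adjusted p = 0.000723 with an estimated correlation. Iron acquisition had 27 of 38 up and 0 down (1.47; entF 3.18, fhuE 3.48; 30 up adjusted over the list alone; adjusted p = 0.542 with an estimated correlation). The TCA cycle had 9 of 22 up and 2 down (pck 2.87, aceA 1.62; 10 up adjusted over the list alone) and H-NS-silenced loci 10 of 39 down and 1 up (appY -2.31). For this pair, too, adjusted p = 0.542 with an estimated correlation, and with total sense values 4 TCA genes rose and 3 fell, and 16 H-NS-silenced loci fell. RpoS genes had 26 of 36 down and 4 up (-0.97; hdeA -3.00; 27 down adjusted over the list alone) and heat shock 8 of 21 down and 0 up (ibpA -1.72), with adjusted p = 0.213 and 0.605 with an estimated correlation. The value of ptsG was -2.42. In all, 1313 sense ORFs were called, 727 up and 586 down (407 and 196 at least 2-fold). With total sense values 501 went up and 1192 down, and with sense plus antisense totals 504 up and 1177 down, as the median of all ORFs moved from 0 to -0.25. With the 500 highest ORFs 621 went up and 684 down. Of the named enzymes and factors, topA (-0.41, adjusted p = 0.0624) and recG (-0.39, 0.0905) did not pass, but did so with total sense values and with the 6 libraries alone. The values of nusG (-0.11, 0.692) and rnhA (0.09, 0.804) did not pass either, with signs that changed between settings.

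Antisense was called at 620 ORFs in WT_glycerol, 238 up and 382 down (median -0.11). There were 182 up and 866 down with total sense values, 184 up and 872 down with sense plus antisense totals (median -0.31 for both), and 359 up and 287 down when scaled by the antisense values. The largest rises were at glpT, at 261 ± 73.5 against 2.95 ± 1.69 ppm (6.32, SE 0.279, adjusted p = 1.23e-13). Next were yzgL (b3427, positions 3561747 to 3562028), at 525 ± 37.8 against 8.35 ± 1.35 (5.90, SE 0.255, adjusted p = 8.34e-14), and glpA, at 37.6 ± 11.3 against 0.148 ± 0.0814 (5.84, SE 0.236, adjusted p = 4.08e-14). Antisense fell most at ycdP (b1021, 1085329 to 1085742; -2.84, SE 0.286, adjusted p = 1.49e-07) and yhiF (-2.82, SE 0.259, adjusted p = 4.33e-08). Antisense rose at 9 of 9 glycerol genes, 47 of 52 flagellar genes (48 adjusted over the list alone; cheY 2.94, motA 2.48) and 29 of 64 CRP-cAMP genes with 1 down (30 up and 3 down adjusted over the list alone; cstA 2.63). These calls held, with adjusted p = 0.0036, 0.0118 and 0.0455 with an estimated correlation. Iron acquisition (18 of 38 up, 19 adjusted over the list alone; feoA 2.75), RpoS (14 of 36 down, 1 up, and 19 down and 2 up adjusted over the list alone; hdeB -2.32) and TCA genes (7 of 22 up, 1 down, and 8 up and 2 down adjusted over the list alone) were called too, but with adjusted p = 0.227, 0.352 and 0.837 with an estimated correlation. With total sense values 4 TCA genes rose and 2 fell (median 0.05 against 0.32), 22 RpoS genes fell (-0.88 against -0.68), and 26 CRP-cAMP genes rose and 8 fell (0.17 against 0.425). Single libraries moved the antisense counts. Without WT_glycerol replicates 1, 2 and 3 in turn they were 192 up and 251 down, 181 up and 286 down (median -0.158), and 253 up and 262 down (median -0.055). Without WT_glucose replicates 1, 2 and 3 in turn they were 185 up and 310 down (median -0.188), 313 up and 339 down (median -0.003), and 191 up and 227 down. The ratio was called for 586 ORFs, 133 up and 453 down. The rises were 86 without WT_glycerol replicate 1 and 81 without replicate 2, and with voom weights there were 77 up and 295 down. Its median of -0.06 rests on single libraries: it was -0.165 without WT_glycerol replicate 2, -0.15 without WT_glucose replicate 1, 0.008 without WT_glycerol replicate 3 and 0.01 without WT_glucose replicate 2. ORFs with a convergent neighbour had a median antisense change of -0.30 against -0.05 for codirectional ones (permutation p = 1e-05, and 0.00025 by circular shifts). The difference of -0.25 lay between -0.334 and -0.200 without any 1 library, and the values per library had an exact permutation p of 0.1.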

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

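Effects of the deletions that differ by a direct test between drho_UvsW and dnusG_UvsW are given here. Of the sense ORFs whose difference passed that test, 112 rose in drho_UvsW and fell in dnusG_UvsW, and 79 did the opposite. For antisense ORFs these numbers were 77 and 18. With sense plus antisense totals, and without asking for the direct test, the sense counts were 75 and 118, so their balance turned with the scaling, and the antisense counts were 49 and 14. Gene lists with a camera call for the difference, as median log2 values of drho_UvsW minus dnusG_UvsW on the sense strand, were e14 (1.263), flagella (1.191), CP4 (1.182), glycerol (0.896), H-NS-silenced loci (0.529), Qin (-1.077), iron (-0.898), transcription elongation (-0.76), SOS (-0.605), R-loop enzymes (-0.516), the TCA cycle (-0.372) and ribosomal proteins (-0.326). For antisense they were DLP12 (1.637), flagella (1.583), capsule (1.58), CP4 (0.967), glycolysis (-0.108, whose sign changes with the scaling), transcription elongation (-0.707) and ribosomal proteins (-0.769). With the 500 highest ORFs the sense medians of the TCA cycle and of ribosomal proteins came to -0.082 and -0.034. These list calls were lost with an estimated correlation, as given above.

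The antisense rise in both deletions was weighed first. Genomic DNA in the library would add a similar density to every ORF. The 5th percentile of the density added was -121.1% of the median in drho_UvsW and -387.8% in dnusG_UvsW. These values were computed with the size factors alone, on which the antisense falls depend. With the 500 highest ORFs the called falls went from 348 to 91 in drho_UvsW and from 372 to 120 in dnusG_UvsW. The percentiles therefore cannot decide whether DNA is the whole cause. A part from DNA stays open too: the 5th percentile of antisense density in the deletions was 37.5% and 45.3% of the median density added. Sense reads on the wrong strand would add a fixed share of each ORF's sense value. The antisense percent of the 200 highest sense ORFs would then rise too. It was 2.479% in WT_UvsW, 2.764% in drho_UvsW and 2.46% in dnusG_UvsW. Its change was 1.7% and -0.3% of the change of the percent over all ORFs. The lowest median antisense log2 change over the scalings from sense or total values was 1.846 and 0.87. These values argue against both wrong-strand reads and scaling. The lowest share in a deletion library, 21.603% for drho_UvsW and 11.024% for dnusG_UvsW, lay above the highest in WT_UvsW, 5.404%, which restates the rise and tests no cause of it. Genotype and inoculum, and in dnusG_UvsW the IPTG level, differ together in these comparisons and stay open.

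Transcription running on from a convergent neighbour was weighed next. Across ORFs with such a neighbour, the antisense density gained rose with the sense density of the neighbour (Spearman's correlation 0.456 in drho_UvsW and 0.397 in dnusG_UvsW). With the sense density of the ORF itself it was -0.362 and -0.089, and for codirectional neighbours -0.441 and -0.169. Read-through may therefore add to antisense RNA at these ORFs. ORFs with a codirectional neighbour had a median rise as well, 1.995 in drho_UvsW (1.588 at convergent ones) and 0.848 in dnusG_UvsW (0.929 at convergent ones). The adjacent 3′ ORF cannot be the source there, but transcription from convergent genes farther away was not tested.

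Sense changes along the chromosome were weighed against gene dosage between the origin and terminus of replication. Spearman's correlation of the change with the distance from the origin was -0.009 in drho_UvsW (permutation p = 0.8325 over all circular shifts of 4066 ORFs) and 0.016 in WT_glycerol (permutation p = 0.8079). Values this near 0 argue against dosage, which needs a trend along the chromosome. In dnusG_UvsW it was -0.159 (permutation p = 0.1714), with a median log2 change of 0.44 in the nearest quintile and -0.15 in the farthest, and dosage and position of the genes cannot be told apart there because the shifts give trends of this size.

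The 6 libraries of a comparison allow 10 splits, too few for a share under 0.1. In each of the 15 results 1 split, the real one, gave as many ORFs. The real and highest other counts for sense, antisense and ratio were 3166 and 0, 3437 and 0, and 3140 and 0 for drho_UvsW, and 2819 and 0, 2864 and 0, and 2300 and 0 for dnusG_UvsW. For WT_UvsW against WT_glucose they were 872 and 42, 489 and 178, and 331 and 14. For WT_glycerol they were 1313 and 0, 620 and 3, and 586 and 0, and for the deletions against each other 2419 and 0, 2710 and 0, and 2531 and 0.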

How the results depend on the processing

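Of 192 named ORF results, 3085 of 3124 alternative values kept direction and side of the threshold, 9 became weaker, 7 stronger and 23 reversed. Of 139 other results, 433 of 539 alternative values stayed the same. Among them were those added after seeing the data, the circular shifts of neighbour classes and the thrL exchange described below. The cause was not tested for the changes below, except that a fit of 6 libraries, or of 1 fewer, rests on fewer samples.

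ORFs called in WT_UvsW against WT_glucose moved most. With the 6 libraries alone there were 535 on the sense strand, 182 on the antisense strand and 127 for the ratio. Antisense gave 779 with total sense values, 740 with sense plus antisense totals, 880 with the 500 highest ORFs and 282 with antisense scaling, and 254 to 618 with 1 library left out (254 without WT_UvsW replicate 1, 268 without WT_glucose replicate 1). The ratio gave 185 with voom weights and 241 to 533 with 1 library left out (533 without WT_UvsW replicate 3). In WT_glycerol, antisense gave 1048 with total sense values and 1056 with sense plus antisense totals, and the ratio 372 with voom weights. Without the 100 ORFs of highest antisense value the antisense share differences were 14.014 (drho_UvsW), 5.429 (dnusG_UvsW) and 8.585 (between them). With sense plus antisense totals 576 sense and 94 antisense ORFs fell in both deletions. The replicate number as a block gave 3167, 2836, 890, 1306 and 2421 sense ORFs in drho_UvsW, dnusG_UvsW, WT_UvsW, WT_glycerol and the direct comparison. It changed the call of 0 named ORFs. Among the 5 comparisons made, residuals of same-numbered libraries correlated in every pair in the direct one on the sense strand (r 0.285 to 0.293). In every other comparison and strand the lowest pair was at 0.019 or below. Different-numbered sense libraries of WT_glucose and WT_UvsW reached 0.48, so correlations of this size do not settle whether cultures were paired. Outside them, same-numbered sense libraries of WT_glucose and drho_UvsW, which were not compared, also correlated (r 0.24 to 0.331).

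Reversed genes were nusG in drho_UvsW (0.082 with total sense values, 0.384 with the 500 highest ORFs), recG in dnusG_UvsW (0.348, 0.248 with both totals and 0.505, and -0.306 to 0.048 with 1 library left out) and rnhA there (0.484, 0.385, 0.641, 0.009 with 6 libraries, and -0.174 to 0.217). In WT_UvsW topA gave -0.046 with 6 libraries and -0.135 to 0.077 with 1 left out. In WT_glycerol nusG gave -0.233 to 0.075, and rnhA -0.183 and -0.177 with total sense values and both totals, and -0.055 to 0.378. Between the deletions topA gave 0.06 with the 500 highest ORFs.

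List calls lost with an estimated correlation had these adjusted p. In drho_UvsW sense: 0.167 for CP4 and H-NS, 0.17 for capsule, DLP12, SOS and TCA, 0.189 glycolysis, 0.243 amino acid, 0.378 RpoS, 0.457 heat shock, 0.497 ribosomal. In drho_UvsW antisense: 0.287 for CP4, glycolysis, Rac, ribosomal and transcription, 0.304 amino acid and DLP12, 0.34 capsule, H-NS, heat shock and TCA, 0.616 flagella. In dnusG_UvsW sense: 0.222 for amino acid, capsule, DLP12 and H-NS, 0.232 flagella, glycolysis, Qin and SOS, 0.278 TCA, 0.388 RpoS, 0.415 heat shock, 0.609 ribosomal. In dnusG_UvsW antisense: 0.351 for amino acid, CP4, glycolysis, H-NS, Rac, ribosomal, heat shock and TCA, 0.497 DLP12, 0.558 capsule, 0.637 Qin. In WT_UvsW sense: 0.0983 for e14 and TCA, 0.911 ribosomal, RpoS and heat shock. In WT_UvsW antisense: 0.152 flagella, 0.607 SOS and TCA, 0.853 capsule, heat shock and ribosomal. In WT_glycerol sense: 0.213 RpoS, 0.542 iron, H-NS and TCA, 0.605 heat shock. In WT_glycerol antisense: 0.227 iron, 0.352 RpoS, 0.837 TCA. Between the deletions, sense: 0.244 CP4, 0.259 e14, flagella, glycerol, SOS and transcription, 0.26 Qin, 0.475 TCA, 0.484 H-NS and R-loop, 0.635 iron, 0.755 ribosomal. Antisense: 0.733 for capsule, CP4, DLP12, glycolysis, ribosomal and transcription, 0.906 flagella. With sense plus antisense totals iron in drho_UvsW sense passed (0.0436), while RpoS in WT_UvsW sense (0.132) and capsule in WT_UvsW antisense (0.0653) did not.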

Other observations

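In WT_glycerol replicate 3 the values of thrL, the leader peptide ORF of the threonine operon, stand in the opposite columns from those of the other replicates. Sense and antisense base counts were 791 and 405080, against 389899 and 540 in replicate 1 and 470034 and 610 in replicate 2. With the strands of this ORF exchanged in that library, an alternative added after seeing the data, the antisense share of WT_glycerol minus WT_glucose was -0.388 percentage points.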
